A study of Caenorhabditis elegans with 2 samples.

How the data were processed

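Each of the 2 samples is a biological replicate of 1 group, per the labels: whole hermaphrodite L1 larvae of a strain with tagged Y116A8C.19, immunoprecipitated with an antibody against GFP after sonication. The deposited files are lists of regions on 2 genome builds, ce10 and ce11, with 8 lists in all. For each build there is a list per replicate of peaks and background that served as input for IDR, a pooled list and an IDR-thresholded list. Per the file headers and accompanying notes, the pooled list was called on both alignments with a control, and the IDR list was derived from both replicate lists and the pooled list. The aligner, the peak caller, its version and the IDR threshold are not given in the sources used here.

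The deposited lists hold, for each region, a signal value of the authors, whose scale and normalization are not given in the sources used here. It was used only to rank and describe regions within a list. The deposited lists also hold a −log10 q-value, which was 2.658 for all 198 IDR peaks in ce11 and so was not used to rank them. The column for p was empty in every list. A list keeps no read counts, so depth is unknown and intervals cover counting error of regions only. The per-replicate lists held 22595 and 22358 regions in ce11. Regions had a common width, 390 bp in the IDR list, apart from 19 narrower peaks of 110 to 196 bp, 17 of them among the 25 strongest. In the ce10 list of replicate 1 a single region was 700397 bp wide, and ce10 lists were used for counts, signals and chromosome shares only. Coordinates were never converted between builds.

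Genes came from the Ensembl release 115 annotation and sequence from the RefSeq genome of the same build, WBcel235. Each region was placed by its summit. A promoter window ran from 1000 bp upstream to 200 bp downstream of the annotated 5′ end of a gene. Annotation classes were assigned in the order promoter window, 5′ UTR, coding exon, 3′ UTR, intron, non-coding gene and intergenic. Background regions were the 44484 nuclear regions of the per-replicate ce11 lists that overlapped no IDR peak. Random draws (10000) took as many background regions per chromosome as there were IDR peaks. A p from random draws is written below as a permutation p, although nothing was permuted in them. Replicate overlap needed at least 1 bp. Chromosome counts were tested against length with 100000 Monte Carlo draws and exact binomial tests, GC content with 100000 sign-flip permutations, and gene lists and k-mers with Fisher exact tests. The tests of gene lists, annotation classes, chromosomes and 6-mers were adjusted, each within its family, by the Benjamini-Hochberg method at 0.05. The tests of the 8-base elements and those of the closing section were not adjusted.

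The groups, the tests of the design, 117 of the 141 alternatives and the 34 gene lists were set before the data were examined, and 24 alternatives and the tests of the 8-base elements were added later. For chromosomes the design named the Monte Carlo test and a binomial test for X alone. The binomial tests of the other chromosomes, including III, and their adjustment were not part of it. Of the lists, 33 had at least 5 annotated members and were tested. Of 606 symbols written out in the lists, 596 matched the annotation. Named genes were those of the 25 strongest IDR peaks, up to 4 strongest bound members of each list, Y116A8C.19 and unc-119, and the tRNA, snoRNA, snRNA and rRNA genes in any of those windows, read here as every such gene with an IDR summit in its promoter window. A narrower reading, windows of the 25 strongest peaks alone, would name fewer of the snoRNA genes. The search for 8-base elements was added later: the strongest 8-mer on peaks of odd rank, and the strongest sharing no 5-mer with it, were counted with up to 1 mismatch on either strand. Alternatives included the 99 stronger peaks, the best 198 nuclear regions of either replicate alone, other windows, other backgrounds, other k-mer lengths and the ce10 list.

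The tests were tested on simulated data, as sets of 198 regions drawn from the background. All 118 planted promoter regions and all 15 planted ribosomal protein genes were recovered, and a 6-mer planted in 59 regions was found in 62. The planted regions were placed inside the windows counted, and the 6-mer was written into the sequence. These recovered counts thus check the code only and do not measure sensitivity. The run with planted ribosomal protein genes called 2 lists enriched, though no other list was planted. In 20 sets without planted signal the promoter test gave 0 calls and the gene lists gave 1 call in all. These sets, drawn from background, were not gathered at promoters as the IDR peaks were. They therefore do not show how often the list test errs for such peaks. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.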

Results

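Chromatin immunoprecipitation followed by sequencing was used to map where the protein Y116A8C.19 sat on the genome of the nematode Caenorhabditis elegans. The reference annotation describes Y116A8C.19 as a protein with a C3H1-type zinc finger domain. The worms carried an integrated transgene that makes the protein with GFP and FLAG tags at its C-terminal end, and an antibody against GFP pulled down the bound DNA. Whole hermaphrodite L1 larvae were collected 6 hours after release from starvation-synchronized hatching. There was 1 group with 2 biological replicates and no second condition, so the comparisons are between the replicates, between bound and background regions, and between gene groups. The control experiment was not analysed here, and the read depth behind the lists is unknown. All positions are in ce11 (WBcel235).

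The authors' IDR-thresholded list held 198 sites (IDR peaks, where IDR is the irreproducible discovery rate). These were the 198 strongest regions of the pooled list by signal, so a single peak need not be strong in both replicates. The largest signal, 247.7 in the authors' units, lay on chromosome III from 7520752 to 7520947. Its summit fell 6 bp inside the annotated 5′ end of cux-7 and at -624 bp from that of lig-4, which encodes the DNA ligase of end joining, with C07H6.2 between them (negative distances are upstream). The next was on chromosome I from 11374353 to 11374533 with signal 226.7, between the divergent genes F56G4.6 and wbp-4. The peak of rank 3, on chromosome III from 11946464 to 11946657 with signal 225.7, lay in an intron of Y56A3A.7, 454 bp inside the gene. The peak of rank 4 (signal 188.7, chromosome III from 8307470 to 8307653) lay upstream of F10E9.5, F10E9.7 and F10E9.4, and that of rank 5 (signal 185.9, chromosome I from 461671 to 461832) lay at -268 bp from W04C9.4.

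The 25 strongest peaks had signals from 133.2 to 247.7, and 21 of them had their summit in a promoter window. Genes of known function beside them included ced-5, needed for the engulfment of dying cells, tasp-1, a threonine aspartase, and thoc-5, a subunit of the THO complex of mRNA export. Others were cyn-10, a cyclophilin, mppb-1, a subunit of the mitochondrial processing peptidase, mrt-2, a checkpoint gene needed for telomere maintenance, and eif-3.B, a translation initiation factor subunit. The chromosome condensation gene hcp-6, with let-630 on the other side, and pinn-1, a prolyl isomerase, completed this set. Genes without a function stated here were F25H9.6, F25H9.7, C47E8.4, Y73B6BL.29, lrpr-1, K01G5.10, T07F10.3, F01D4.5, tag-124, E02H1.1, C53B4.3 with the piRNA gene 21ur-13444, and C49A9.10. The summit of the C47E8.4 peak also lay within the gene hsp-90. The remaining peaks of the 25 lay in an intron of gly-5, 568 bp inside the gene, at -2617 bp from F58D12.3, and at -181 bp from the pseudogene WBGene00020028. All 25 ranked 32 or better in the list of replicate 1 and 50 or better in that of replicate 2.

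The replicates shared many of their strongest sites. Of the 198 best regions of replicate 1, 132 (66.7%, exact 95% interval 59.6 to 73.2%) overlapped one of the 198 best of replicate 2, against a mean of 2.25 in random draws from the whole list of replicate 1. The one-sided permutation p was 1e-04, the smallest that 10000 draws can give. The IDR list was derived from both replicate lists and held the strongest pooled regions. The values over IDR peaks that follow thus describe it and are no evidence that the replicates match. Every IDR peak overlapped a region of replicate 1, and 196 of 198 overlapped a region of replicate 2. Of the IDR peaks, 177 were among the 198 best of replicate 1 and 148 among those of replicate 2, and 16 ranked past 1000 in replicate 2. Across the 196 peaks seen in both lists, signals had a Spearman correlation of 0.559 (95% bootstrap interval 0.449 to 0.655). Over all 7052 overlapping regions, which include background, it was 0.173, and 0.264 where summits lay within 100 bp. The IDR peaks of rank 61 and 164 overlapped the same region in each replicate, as did those of rank 90 and 148, so these values entered more than once. Regions are not replicates, so no p was computed for these correlations.

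**Figure D1:**
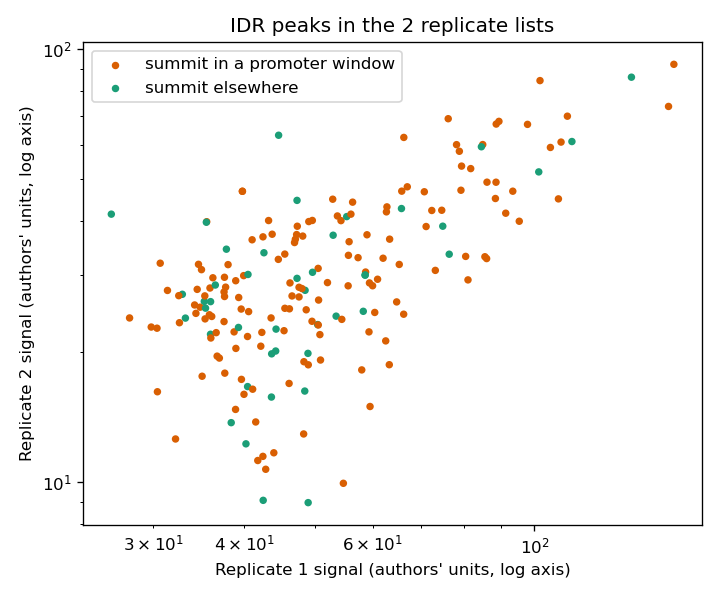
Signal of each IDR peak in the list of replicate 1 (x axis) and of replicate 2 (y axis), in the authors' units on log axes. Each point is 1 of 196 peaks, coloured by whether the summit lay in a promoter window. Among these IDR peaks the signals of the replicates had a Spearman correlation of 0.559, against 0.173 over all 7052 overlapping regions. The IDR list was derived from both replicates, so the value of 0.559 is no evidence that the replicates match.

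Binding was concentrated just upstream of genes. The summit of 154 of 198 IDR peaks (77.8%, exact 95% interval 71.3 to 83.4%) lay between 1000 bp upstream and 200 bp downstream of the annotated 5′ end of a protein-coding gene, against 25.4% of background regions. The one-sided permutation p was 1e-04, the smallest the draws can give. The median distance to the nearest protein-coding 5′ end was 245 bp for IDR peaks and 1484 bp for the 44484 background regions, and 80.3% of IDR summits lay upstream of that end against 44.4% of background summits. No summit fell in a coding exon outside these windows, which allows a share of up to 1.52% as 3 counts of the total (exact two-sided 95% bound 1.85%), where 19.1% of background regions did. Introns held 22 peaks (11.1% against 29.1%) and intergenic sequence 20 (10.1% against 20.2%), with adjusted permutation p of 0.00035 for coding exons, introns and intergenic sequence. No summit lay in a 3′ UTR against 2.44% of the background, with an adjusted permutation p of 0.0174, a call lost among the 99 stronger peaks (adjusted permutation p 0.252). The intergenic share was 5.05% among the 99 stronger peaks. In 5′ UTRs and in non-coding genes there was 1 peak each, and neither share passed the test, with adjusted permutation p of 0.968 and 0.0553. Many worm transcripts are trimmed by trans-splicing, so an annotated 5′ end can lie downstream of the start of transcription.

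**Figure D2:**
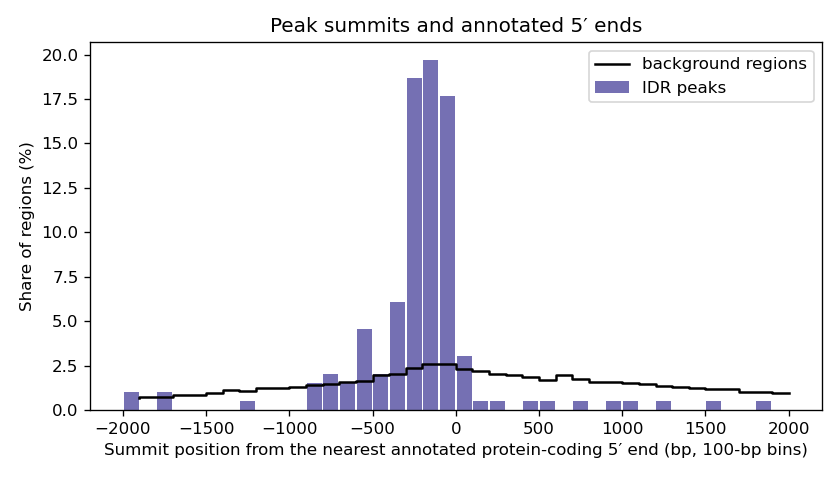
Position of the summit relative to the nearest annotated protein-coding 5′ end (x axis, bp, negative is upstream) and share of regions (y axis, %). Bars are the 198 IDR peaks and the line is the 44484 background regions, in 100-bp bins. IDR summits gather just upstream, with a median distance of 245 bp in either direction.

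Ribosomal protein genes and chromatin genes had an IDR peak in their promoter window more often than other genes. Of 33 gene lists tested, 5 held more bound members and 1 held fewer by a two-sided Fisher exact test adjusted over the lists. Lists of protein-coding genes were compared with other protein-coding genes and lists of RNA genes with all other genes, so odds ratios of the 2 kinds are not on the same footing. Of 82 cytosolic ribosomal protein genes, 9 had an IDR peak in their window (odds ratio 10.7, 95% interval 4.66 to 21.9, adjusted exact p 5.67e-06). The odds ratio fell to 6.38 when only genes with any listed region in their window were compared. Among peaks with a sequence element, described later, the odds ratio was 5.6 and the call was lost (adjusted exact p 0.207). The strongest were rpl-3 (signal 124.1), rpl-20 (108.7), rpl-15 (107.9) and rpl-35 (84.5). Chromatin genes had 6 of 47 bound (odds ratio 12.6, 95% interval 4.32 to 30.2, adjusted exact p 0.000147). This call was lost among the 99 stronger peaks (odds ratio 6.98, adjusted exact p 0.201) and among peaks with an element (6.52, adjusted exact p 0.341). The chromatin genes included lin-35, the worm retinoblastoma gene (99.4), the histone methyltransferase gene set-16 (77.2), ekl-4 (73.7), and the acetyltransferase gene mys-1 (67.6). The peak of ekl-4 was also that of the ribosomal gene rps-20, and lin-54 shared a peak with rpl-12, so the lists are not independent. The summits counted for rpl-20, rps-23, rps-20, rps-26 and rps-12 lay nearer the 5′ end of another protein-coding gene. So did those counted for lin-35, set-16 and lin-54. For these genes the test cannot tell binding at the listed gene from binding at its neighbour. The genes rps-20, rpl-12, lin-54, rps-23, rps-26 and rps-12 were named after their values were seen.

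Genes for snRNAs and snoRNAs were also bound more often, those for snoRNAs in part through the peaks of ribosomal protein genes. All other genes here include the rarely bound piRNA genes, and without these, an alternative added later, the odds ratios were 4.51 for snRNA genes (adjusted exact p 0.0402) and 4.47 for snoRNA genes (adjusted exact p 0.00019). Of 129 snRNA genes, 5 had an IDR peak (odds ratio 6.33, 95% interval 2.01 to 15.3, adjusted exact p 0.01), and this call was lost without replicate 1 (odds ratio 3.8, adjusted exact p 0.176) and among peaks with an element (2.36, adjusted exact p 1). It was also lost among the 99 stronger peaks, where 3 genes were bound and the odds ratio was no lower (7.82, adjusted exact p 0.0838). The bound snRNA genes were sls-2.4 (signal 121.3), sls-2.2 (90.3) and sls-2.1 (75.6), which encode the SL2 spliced leader RNA, with R07E5.16 (95.4) and sup-6 (65.6). Of 346 snoRNA genes, 13 were bound through 11 peaks (odds ratio 6.27, 95% interval 3.26 to 11, adjusted exact p 5.67e-06), a call lost among the 99 stronger peaks (odds ratio 3.85, adjusted exact p 0.187). K11H12.12 and K11H12.13 shared the peak of rpl-15 (107.9), followed by Y53F4B.47 (88.3), F28D1.13 (79), ZK994.7 (66.1), F39B2.14 (66), W06H8.17 (65.9), C06A1.9 (62.4), T27A8.8 (59.9), F54E7.10 and F54E7.11 (59.1 for a shared peak), F59C6.15 (58.1) and K07C5.11 (55.2). The peaks of F28D1.13, of F39B2.14 and of F54E7.10 with F54E7.11 were those of rps-23, rps-26 and rps-12, so 6 of the 13 snoRNA genes were counted through ribosomal protein peaks and the lists are not separate evidence. These rps genes were named after their values were seen. The summits counted for Y53F4B.47, W06H8.17, C06A1.9, F59C6.15 and K07C5.11 also lay in promoter windows of protein-coding genes. Those of ZK994.7 and T27A8.8 lay in an intron and in intergenic sequence. Peaks gathered at protein-coding promoters in general, so the test cannot tell binding at most of these snoRNA genes from binding at the protein-coding genes beside them. The piRNA genes, germ line small RNAs, were bound less often, 18 of 15363 (odds ratio 0.13, 95% interval 0.0756 to 0.209, adjusted exact p 4.75e-28). These 18 came from 5 peaks, beside 21ur-13444 (135.3), 21ur-6245 (84.1), 21ur-12468 (70.3), 21ur-11261 (63) and a cluster of 14 at a single peak. The test treats such neighbours as independent, so its interval and p are too narrow and too small. Without replicate 2 only 4 piRNA genes were bound (odds ratio 0.0295), and over all alternatives the odds ratio ranged from 0.0267 to 0.252.

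Chaperone genes gave a weaker result. With 4 of 62 bound (cct-8 67, hsp-60 64.8, dnj-12 60.1 and dnj-29 57), the odds ratio was 5.88 (95% interval 1.54 to 16.1, adjusted exact p 0.0336). Each of these 4 summits lay nearer the 5′ end of another protein-coding gene. The test thus cannot tell binding at the chaperone genes from binding at those neighbours. The call was lost without replicate 2 (adjusted exact p 0.46), with the window of 500 to 100 bp (0.118), against genes with any listed region (0.0739) and among peaks with an element (adjusted exact p 1). Among the 99 stronger peaks none had its summit in the promoter window of these 62 genes, though the peak of rank 8 lay within hsp-90. Lists that did not pass but had bound members were translation factors, 2 of 42 (eif-3.B 136.9 and eif-3.E 56.1), splicing proteins, 2 of 41 (prp-19 117.5 and mog-4 82.5), and cell cycle genes, 2 of 42 (lin-35 and pcn-1, the replication clamp, 67.4). The tRNA genes had 2 of 612 (WBGene00014564 67.4 and WBGene00023221 66.1). Single members were bound among proteasome (rpn-11, 59), oxidative phosphorylation (cox-5A, 95.6), collagen (col-71, 65), sperm (spe-48, 55.8) and heterochronic or microRNA genes (mir-354, 73.7).

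Most lists of genes that mark tissues had no peak. In 18 lists no member was bound, and none of these passed the test, which does not show that they are never bound. They included 40 body wall muscle, 23 pharynx, 35 intestine, 50 hypodermis and 68 neuron genes, 43 germ line genes, 53 genes of insulin signalling and starvation, 81 histone genes, 27 lysosome genes and 20 rRNA genes. Transcription factor lists were also without a peak, at 274 nuclear receptors, 96 homeobox genes and 170 other factors, as were 140 neuropeptide, 202 detoxification and 351 innate immunity genes. The last had an unadjusted exact p of 0.0387 and an adjusted exact p of 0.183. Markers of adults (16 yolk and eggshell genes) and of embryos (32 genes) had no peak. Few protein-coding genes were bound, so the shorter lists have too few members for an absence of peaks to mean much.

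**Figure D3:**
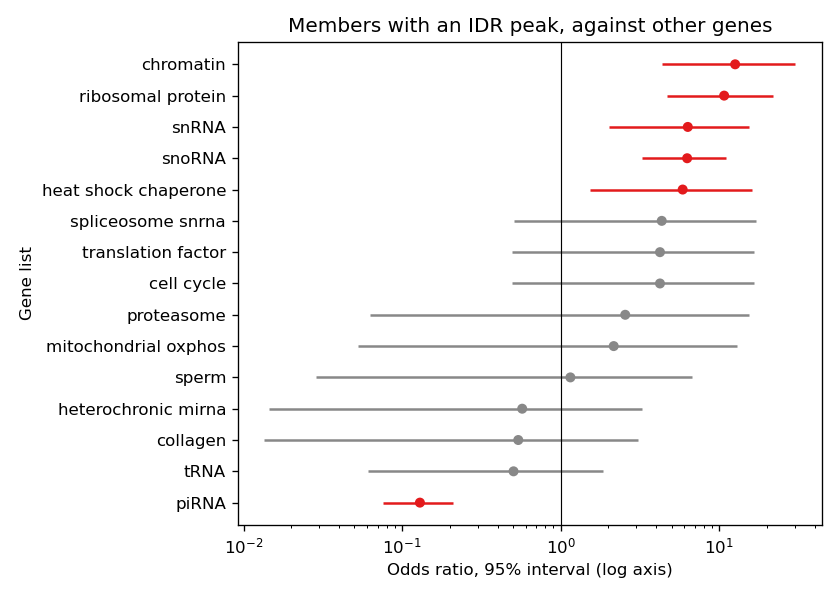
Odds ratio of having an IDR peak for members of each gene list with at least 1 bound member (x axis, log scale, with 95% intervals), against other protein-coding genes or, for RNA genes, all other genes. Red lists passed an adjusted exact p of 0.05, grey lists did not. Chromatin genes are highest at 12.6 and piRNA genes lowest at 0.13.

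Chromosome III carried the most binding for its length and the X chromosome the least. Chromosome III held 54 IDR peaks (27.3%, exact 95% interval 21.2 to 34%) where its length predicts 27.2, or 3.92 per Mb, with an adjusted exact binomial p of 4.38e-06. The X chromosome held 17 (8.59%, exact 95% interval 5.08 to 13.4%) where length predicts 35, or 0.959 per Mb, with an adjusted exact binomial p of 0.00112. Among the 99 stronger peaks the share on X was 2.02%. The other chromosomes, with 26 on I, 34 on II, 32 on IV and 35 on V, did not pass the test against their length, with adjusted exact binomial p from 0.589 to 0.708. Over all 6 chromosomes the chi-square was 37.7, with a Monte Carlo p of 1e-05, the smallest that 100000 draws can give.

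**Figure D4:**
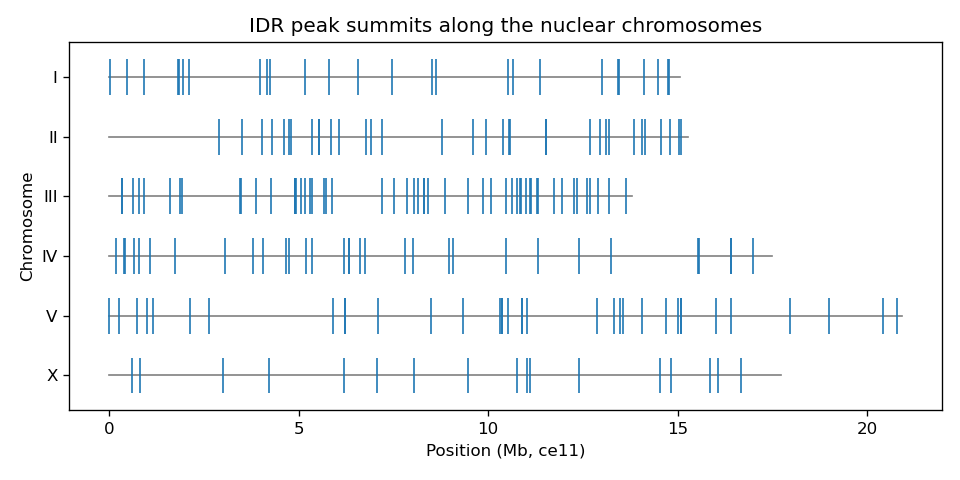
Each vertical mark is the summit of 1 of the 198 IDR peaks along its chromosome (x axis, Mb, ce11). Chromosome III holds 54 peaks and the X chromosome 17.

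Short sequences recurred under the peaks. With reverse complements merged, 131 6-mers were more frequent within 75 bp of the summits than in windows 500 bp to either side, by a one-sided Fisher exact test with adjustment. The strongest was GGCCTA, in 31.3% of the 198 peaks and 2.04% of 392 flanks (adjusted exact p 4.51e-21), followed by CTAGGC in 29.3% and 1.53%. The test took a peak and its own flanks as independent windows, as did the tests of the 8-base elements below. Their p-values are thus approximate. Against background windows of the same chromosome and GC content 107 6-mers passed, of which 72 were among the 131, so many of the 131 depend on the choice of background. With the 99 stronger peaks alone 55 6-mers passed. When 6-mers were found on peaks of odd rank only, 46 of 53 passed again on peaks of even rank. Extending the search to 8 bases, an added step, gave GAGTACAC and CTAGGCCA on the peaks of odd rank. By two-sided Fisher exact tests with up to 1 mismatch, GAGTACAC lay in 33.3% of the 99 peaks of even rank against 5.64% of flanks (exact p 1.26e-09), and CTAGGCCA in 37.4% against 4.62% (exact p 1.41e-12). Both lay together in 19.2% of these peaks and in none of their 195 flanks, which allows a share of up to 1.54% as 3 counts of the total.

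The summit windows of single sites show how the elements sit. Under the strongest peak, the window on chromosome III from 7520764 to 7520914 spans the 5′ end of cux-7 and reads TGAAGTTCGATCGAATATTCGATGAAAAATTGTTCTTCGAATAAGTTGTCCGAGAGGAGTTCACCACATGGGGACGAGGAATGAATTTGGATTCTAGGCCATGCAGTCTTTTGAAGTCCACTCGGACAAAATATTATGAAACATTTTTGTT. It holds 1 copy of each element, that of GAGTACAC with 1 mismatch as GAGTTCAC. The window upstream of cyn-10, on chromosome II from 6913424 to 6913574, reads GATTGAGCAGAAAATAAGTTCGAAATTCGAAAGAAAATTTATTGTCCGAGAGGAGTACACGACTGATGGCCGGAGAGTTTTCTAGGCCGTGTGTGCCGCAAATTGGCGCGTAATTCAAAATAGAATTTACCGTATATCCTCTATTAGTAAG and also holds 1 of each. In the cyn-10 window the copy of CTAGGCCA has 1 mismatch, as CTAGGCCG. Of the 25 strongest peaks, 23 held at least 1 element and 10 held both, with up to 1 mismatch. These 25 include peaks of odd rank, from which the elements were taken. The summits were also richer in G and C than their flanks, 43.4% against 37.9%, a difference of 5.47 percentage points (SD 9.88 over 198 peaks). It was higher in 138 of 198 peaks, with a two-sided permutation p of 1e-05, the smallest the draws can give.

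**Figure D5:**
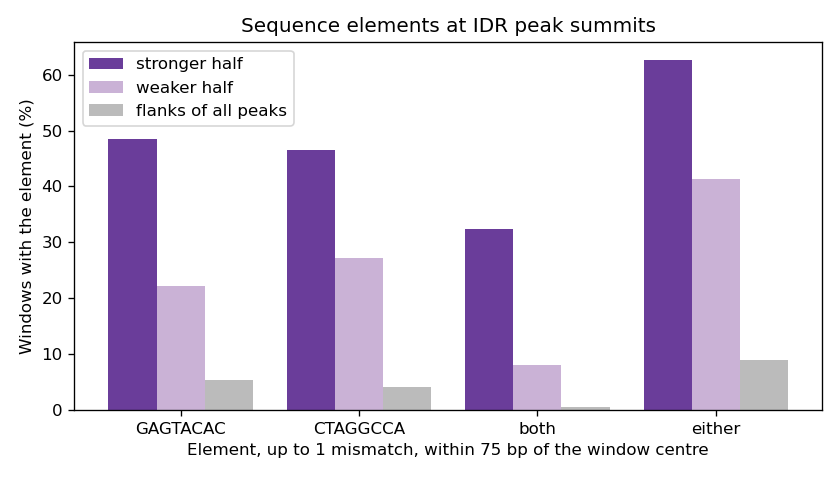
Share of summit windows with each 8-base element (y axis, %), with up to 1 mismatch within 75 bp, for the 99 stronger and the 99 weaker IDR peaks and for the flanks of all peaks. Both elements together lie in 32.3% of the stronger, 8.08% of the weaker peaks and 0.51% of flanks. Peaks of odd rank, from which the elements were taken, are included.

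The IDR list had no peak near the tagged gene or the marker gene of the strain, but these windows are too short to show an absence of binding. No IDR peak lay within 20 kb of Y116A8C.19 (chromosome IV from 17039055 to 17039645, a single exon on the minus strand) or of unc-119 (chromosome III from 10902641 to 10908935), the gene mutated in the strain and commonly rescued with such transgenes, but density predicts only 0.0743 and 0.181 there. The pooled list held 2 and 3 regions, where density predicts 1.07 and 1.42. Within 20 kb of Y116A8C.19 the lists held 8 regions in replicate 1 and 18 in replicate 2, where density predicts 9.18 and 9.41. Near unc-119 they held 16 and 17, where density predicts 10.5 in each. In windows of the same width the 95th percentile was 15 in both lists near Y116A8C.19, and 17 and 16 near unc-119, so the count exceeded it in replicate 2 but not in replicate 1 at both genes. For Y116A8C.19 in replicate 2 the ratio to the predicted count was 1.91 (exact 95% Poisson interval 1.13 to 3.02) within 20 kb and 1.23 within 40 kb.

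The authors' lists on the 2 genome builds differed in length. The ce10 list held 263 IDR peaks against 198 in ce11, a ratio of 1.33, although the pooled lists held 2890 and 2689 regions. Signals at the same rank were nearly equal between builds, with a median ratio of 0.9945 in the IDR lists. In both builds the IDR peaks were the top regions of the pooled list by signal.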

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

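The tests on the recurring sequence were chosen only after the 6-mer result was seen, and the limit to genome copies outside IDR peaks only after the element counts were seen, in each case before the result of the test itself. The ratios over peaks of even rank were added after those over all peaks were seen.

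Signal appeared in data that the tests against background left out. In ce11, replicate 2 had its largest signal in a mitochondrial region from 12259 to 12598, at 3081, with another from 13019 to 13332 at 604.6. These 2 regions held ranks 1 and 2 in the list of replicate 2, so they counted among its 198 best in the replicate overlap. The largest nuclear signal of that list was 92.3, and replicate 1 listed no mitochondrial region.

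GAGTACAC or CTAGGCCA lay under 103 of 198 peaks, and both under 40. Repeat copies that share reads are argued against, since 0 of 103 element windows (0%, upper exact 95% bound 3.52%) had most of their 36-base words repeated in the genome. Base composition is argued against too, since in background windows matched on chromosome and GC the elements were 4.33 and 5.57 times rarer than in IDR peaks of even rank, from which they had not been taken (4.43 and 5.54 over all peaks). A candidate explanation is that binding follows the sequence: both elements lay together in 32.3% of the 99 stronger peaks and 8.08% of the 99 weaker ones (exact p 3.06e-05), and genome copies of the pair lay in pooled regions 4.08 times as often as the same words read backwards. These values met the test as first written, but it counts the peaks in which the elements were found, and among copies outside IDR peaks the ratio was 1.77 with an exact p of 0.0652, which leaves this open.

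The excess on chromosome III was weighed against the unc-119 transgene marker and against the recurring sequence. Extra DNA copies near unc-119 are argued against as the main cause, since 3 IDR peaks lay within 100 kb where 0.808 were predicted, which is 8.18% of the excess of 26.8 peaks and at most 29.7% by counting error. On III, with 13.7% of the length, lay 12.6% of the 1256 genome copies of the element pair (exact binomial p 0.251). Only 41 of these copies lay in IDR peaks, and the same words read backwards had 1632 copies. Most copies may thus be unbound, so their share cannot decide whether bound copies gather on III. Chromosome III held 28.2% of the peaks with an element and 26.3% of those with neither (Fisher exact p 0.873). The excess was thus not confined to peaks with an element. Apart from the recurring sequence no biological explanation was tested, and the cause of the excess stays open.

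The set of bound genes was weighed against strong transcription, which can raise recovery of open DNA. Of 5 lists of strongly transcribed genes, 2 were enriched (ribosomal proteins and chaperones) and histone, tRNA and translation factor genes were not. Every chaperone summit and several of the ribosomal protein summits lay nearer the 5′ end of another protein-coding gene. Strong transcription thus cannot be told apart from binding with these lists, and no control experiment was analysed here. Peaks at ribosomal protein, snoRNA and snRNA genes held either element less often than other peaks, 28.6% of 21 against 54.8% of 177 (exact p 0.0357). This is consistent with some peaks at these genes not resting on the sequence, a hypothesis from the same data. Odds ratios among peaks with an element were 5.6 for ribosomal protein, 5.5 for snoRNA and 2.36 for snRNA genes, against 17, 6.89 and 10.5 among peaks with neither, differences that were not tested.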

How the results depend on the processing

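Of 141 alternatives, 117 planned and 24 added after seeing the data, 124 left the result unchanged: tests kept their side of the threshold and, where passed, their direction, counts stayed within 1.5 times whatever their members (against matched background 72 of the 131 6-mers passed again), and correlations and region densities stayed within the 95% intervals of the reported values. The promoter share ranged from 67.2 to 84.8%, and leaving out replicate 1 or 2 gave 71.2 and 75.8%. With the 99 stronger peaks alone, 2 gene lists passed instead of 6 and 55 6-mers instead of 131. There the odds ratios were 6.98 for chromatin, 7.82 for snRNA and 3.85 for snoRNA genes, with adjusted exact p of 0.201, 0.0838 and 0.187. No chaperone gene had a summit in its promoter window there, an odds ratio of 0 with an interval up to 9.61 that does not show a change of direction. The peak of rank 8 lay within hsp-90 but outside the promoter window of that gene. The chaperone call was also lost with the window of 500 to 100 bp (odds ratio 5.33) and against genes with any region in the window (4.72). The 3′ UTR call was lost with the 99 stronger peaks (adjusted permutation p 0.252). Leaving out a replicate (the best 198 nuclear regions of the other) gave odds ratios from 2.96 to 6.47 for chaperones and from 3.8 to 6.82 for snRNA genes, and each call was lost without 1 of the replicates. Peaks with an element alone, added later, passed 2 lists, with odds ratios of 6.52 for chromatin, 2.38 for chaperones, 5.6 for ribosomal proteins and 2.36 for snRNA genes, and the snoRNA call was kept at 5.5. Peaks with neither kept all 6. Requiring summits within 100 bp moved the correlation over all overlapping regions to 0.264. The excess on III and the shortage on X held in every alternative run. Leaving out a replicate cannot be done for the overlap and correlation of replicates or the peak count. No paired analysis was possible because there is 1 group. Depth is unknown and limits which weak sites could be listed.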

Other observations

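Tests in this part were chosen after the peaks were seen. Peaks often sat between genes that lie on opposite strands: of 154 promoter peaks, 66 (42.9%) lay in the windows of protein-coding genes on both strands, against 14.55% of background promoter regions (95% of draws from 9.09 to 20.1%). The two-sided permutation p was 0.0002, the smallest the draws can give. Examples are wbp-4 with F56G4.6 and hcp-6 with let-630.

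Autosomal peaks were not gathered in chromosome centres. The middle one of 3 equal parts of each autosome held 62 of 181 autosomal peaks (34.3%) against 34.5% of background regions on the same chromosomes, with a two-sided permutation p of 1.

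Some spacings of the pair of elements recurred. Counted between their starts with up to 1 mismatch, 10 pairs lay 15 bp and 9 pairs 14 bp apart on opposite strands, and the next most common arrangement was 5 pairs at 29 bp on the same strand. The spacing was not tested against chance.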
